A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

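Total RNA was extracted with hot phenol from wild type BY4741, Δscd6 and Δsbp1 yeast, untreated or after 30 minutes in 0.5% sodium azide, and made into Illumina libraries with an NEBNext RNA II kit, per the labels' protocols. Each of the 6 groups of strain and treatment held 2 libraries, 12 in all, and was taken from the sample titles. STAR 2, Picard, featureCounts and edgeR are named in the submitters' processing notes, without roles or settings. The genome build, the annotation, the strandedness of the counting and the handling of reads with several matches are not given in the sources used here. Reads of a gene and of one overlapping it on the other strand may therefore not be told apart.

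The data analysed were 7 tables of the authors' own comparisons, each with 6352 genes: azide against untreated in each strain, and each deletion strain against the wild type in either condition. Per the file headers each table holds a mean normalised count over libraries (a signal on a linear scale), a fold change, a log2 fold change, a p-value and an adjusted p-value. The mean normalised signal deposited by the authors is identical in all 7 tables. The fold column deposited by the authors is a linear ratio of azide over untreated or of deletion over wild type. The log2 column deposited by the authors is the log2 fold change of the same comparison. How the normalisation, the fold changes and the p-values were computed is not given in the sources used here. The direction was checked on the deleted genes, which are low in their own strain. The adjusted p-value deposited by the authors equals a Benjamini-Hochberg adjustment of their p-value over the 6352 genes to within 4.6e-08. For each deletion strain, the log2 difference from the wild type in azide minus that in untreated cells equalled the difference of azide responses to within 0.001 in every gene. Depth per library and values per library are not in these tables, and no interval that needs them is given.

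The plan fixed before the data were examined was a count model over all libraries, with the authors' fold changes and p-values as the stated fallback where only comparison tables were held. The fallback was used: genes were counted and ranked at the authors' adjusted p under 0.05. Differences of azide responses are not among the authors' comparisons and were derived as follows, a step chosen after the tables were seen. A standard error was implied for each gene as its absolute log2 fold change over the normal quantile of its p-value, where the log2 fold change was at least 0.02 in size, which left out 1412 values over all tables. The variance of a difference was the larger of the sum over both azide responses and the sum over both comparisons with the wild type, the ratio of these routes having a median of 1.00 in either strain. Differences were tested against a normal distribution and adjusted by Benjamini-Hochberg over 6331 genes for Δscd6 and 6329 for Δsbp1. The difference between both deletion strains, over 6142 genes, was added after the data were seen and used the azide responses alone.

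Gene lists were fixed before the data were examined. Those of stress and translation were P-body components, stress granule components, heat shock chaperones, Msn2/4-type general stress genes, Yap1-type oxidative stress genes, cytosolic ribosomal proteins, ribosome biogenesis, and translation initiation and elongation factors. Those of metabolism were nuclear cytochrome c oxidase subunits, other respiratory chain and ATP synthase genes, tricarboxylic acid cycle, glycolysis and fermentation, hexose transporters, glucose-repressed carbon genes, Aft1-type iron genes, hypoxic and heme-responsive genes, ergosterol biosynthesis, Gcn4-type amino acid genes, and methionine and sulfur assimilation. The others were proteasome, Pdr1-type multidrug transporters, histones, cell cycle regulators, mating type a, mating type alpha, meiosis and sporulation, mitochondrially encoded genes, and the auxotrophic markers of BY4741. Of these 28 lists 27 had at least 3 analysed members and were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the log2 fold changes. The test was two-sided with a preset correlation of 0.01 between genes and adjusted by Benjamini-Hochberg over the lists of a comparison. Members past the test are counted with the p-values adjusted over all genes and again adjusted over the list alone. All other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

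Genes are named by a rule set at the same time. It takes SCD6 and SBP1, and in each comparison, among genes with an adjusted p under 0.05 and a mean log2 CPM of at least 4, the 8 largest rises and the 8 largest falls. For differences of responses it takes the 5 and 5 largest. The rule leaves out dubious, tRNA, snoRNA, snRNA and rRNA genes. As applied, it left out only genes that had neither a description nor a match in the reference annotation described below. The expression limit used the authors' mean count over all libraries, where the plan asked for those of the comparison. The rule also asked for groups that do not overlap in their libraries, which could not be checked, and for the deleted genes in every library, for which the deposited values are given instead. Within a list the 2 to 4 passing members with the largest change were eligible, or the 2 with the highest mean where fewer than 2 passed. COX1 and genes of tandem repeats were named after their values were seen.

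A reference annotation of assembly R64, which may not be the build the authors used, matched 5764 of the 6352 identifiers and served only for names, neighbours, repeats and coding length, so no coordinates are printed. Of the 588 unmatched identifiers 585 also lacked a description. Coding length was had for 90.7% of genes, and 97.0% of the lengths were multiples of 3. A gene counted as repeated where at least 80% of its 75-base words occur elsewhere in the genome (52 genes), with 300-base words as a stricter form, and as tandem where at least 50% of its words have another copy within 50000 bases.

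Alternatives were a threshold of 0.01, a change of at least 2-fold and leaving out 208 genes under a log2 CPM of 1. Added after the data were seen were scaling to equal totals or by the median of ratios over group means reconstructed from the tables, leaving out repeated genes or genes without description, and a running median over 301 genes of coding length taken out. For differences the other error routes were used, and for lists correlations of 0.05 and 0.1, ranks, signed z values, and tests without SCD6 and SBP1. The chance correlation and covariance of comparisons with shared controls came from 100 simulations. Intervals of list medians came from 2000 bootstrap draws of a list's genes at 95% and do not measure the spread between libraries.

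The difference test was checked on simulated data for Δscd6 minus the wild type with 6352 genes: it found 30 of 100 genes changed by 1 on the log2 scale and 87 of 100 changed by 2, and called 7 of 6152 unchanged genes (0.114%). The simulated standard errors used the true spread that generated the counts. Whether errors implied by p-values from so few libraries are right was therefore not checked, and the rate of false calls in the data may be higher. With simulated genes drawn independently of each other, the list test called 3.5% of lists without a shift and 99.5% of lists shifted by 1 SD of the simulated values. Lists whose genes vary together were not simulated, so the rate of false calls for such lists was not checked. Smaller shifts, such as many of the list medians given, were not simulated either.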

Results

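RNA was sequenced from 12 libraries of Saccharomyces cerevisiae in 6 groups of 2. The strains were BY4741, a haploid laboratory strain used here as the wild type, and its derivatives lacking SCD6 (Δscd6) or SBP1 (Δsbp1). Each strain was sampled untreated, in exponential growth in rich glucose medium at an optical density of 0.4 to 0.5, and after 30 minutes in 0.5% sodium azide, an inhibitor of cytochrome c oxidase and of ATP synthesis that brings on RNA granules. Scd6 and Sbp1 are RNA-binding proteins with RGG motifs that repress translation and are found in P bodies, the granules that hold decapping and decay factors. The stated question was how the transcriptome of each strain changes under azide.

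The values analysed were 7 comparison tables of 6352 genes each, with a mean normalised read count per gene, a fold change, a p-value and an adjusted p-value. The mean normalised count, taken by the authors' deposited table, ran from 5.55 to 371264 with a median of 589. Neither the depth of a library nor any value per library was used here. The precision was read instead from the standard error that a gene's fold change and p-value imply, whose median was about 0.24 on the log2 scale within a comparison. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Log2 changes are written with Benjamini-Hochberg adjusted p-values in brackets, and a gene is said to rise or fall only where that p is under 0.05.

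The deleted genes were low in their own strains. By the authors' deposited table SCD6 (YPR129W) was at 1.29% of its wild type level in untreated Δscd6 cells (log2 change -6.28, adjusted p = 3.4e-62) and at 4.45% in azide (-4.49, 2.6e-42). SBP1 (YHL034C) was at 0.318% of the wild type level in untreated Δsbp1 cells (-8.30, 1.7e-128) and at 1.28% in azide (-6.29, 3.8e-102), by the same authors' deposited table. The residual signal of each gene rose with azide in its own deletion strain in the authors' deposited table, by 1.40 for SCD6 (0.0036) and by 1.73 for SBP1 (1.9e-05). YHL034W-A, an open reading frame that overlaps SBP1, fell with it in the authors' deposited table and was at -7.78 untreated and -6.38 in azide. Of the genes next to SCD6, ANT1 (-0.43, adjusted p = 0.26, and -0.39, 0.38 in azide) and NAT3 (-0.08, 0.90, and -0.23, 0.71) did not pass the test in the authors' deposited table. Next to SBP1, RPL8A did not pass (-0.16, 0.91, and -0.45, 0.31), while VMR1, a vacuolar ABC transporter, gave 0.41 untreated (0.56) and rose by 0.90 in azide (0.0025) in the authors' deposited table. Of the 4 auxotrophic marker genes of BY4741, 1 was analysed here: HIS3 gave 0.39 (0.55) in untreated Δscd6 and 0.07 (0.97) in untreated Δsbp1 cells in the authors' deposited table. In strains that carry the gene, SCD6 gave -0.39 (0.21) with azide in the wild type and -0.36 (0.22) in Δsbp1, and SBP1 gave -0.28 (0.30) in the wild type and 0.21 (0.47) in Δscd6, in the authors' deposited table. Against the wild type, SBP1 gave -0.41 (0.29) in untreated and 0.08 (0.92) in azide-treated Δscd6 cells, and SCD6 gave -0.21 (0.84) and -0.19 (0.63) in Δsbp1 cells, in the authors' deposited table.

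Azide raised general stress genes in the wild type and lowered genes of ribosome assembly, translation and the cell cycle. Among the genes named by size, the authors' deposited table listed rises of FDH1, formate dehydrogenase (log2 change 7.76, adjusted p = 5.0e-24), of HSP30, a plasma membrane stress protein (7.50, 1.2e-31), and of TPO2, a polyamine exporter (5.79, 6.1e-62). Also risen in the authors' deposited table were TDH1, an isozyme of glyceraldehyde-3-phosphate dehydrogenase (4.88, 2.2e-15), and the less studied genes YER053C-A (6.29, 7.7e-76), FMP48 (5.65, 4.1e-93), TDA6 (5.65, 6.0e-48) and YNR034W-A (5.27, 1.1e-58). The falls in the authors' deposited table included PCL1, a G1 cyclin (-3.92, 5.0e-37), PHO84, the high-affinity phosphate transporter (-3.90, 1.5e-24), HO, the mating-type switching endonuclease (-3.55, 2.1e-49), and RNR1, a ribonucleotide reductase subunit (-3.36, 2.5e-39). Others that fell in the authors' deposited table were RRP12 (-3.24, 9.9e-24), SPB1 (-3.15, 1.1e-32) and DBP7 (-3.02, 1.6e-28), which act in ribosome assembly, and CLB2, a mitotic cyclin (-3.04, 4.9e-30). FDH1 has a near-identical copy and TPO2 shares sequence with TPO3, so their values may mix reads of both genes.

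Of 30 general stress genes of the Msn2/4 type, 27 rose in the wild type and 0 fell (29 and 0 adjusted over the list alone). Their median was 2.19 and the list passed the test against all other genes (adjusted p = 1.1e-33). SPI1 at 4.83, SOL4 at 4.14 and DDR2 at 4.07 were among them in the authors' deposited table. Of 18 Yap1-type oxidative stress genes 10 rose and 0 fell (10 and 0 adjusted over the list alone; median 0.66, adjusted p = 0.0039). Sulfiredoxin SRX1 was at 3.02 and CCP1 at 2.50 in the authors' deposited table. Of 16 hypoxic and heme-responsive genes 8 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.72, adjusted p = 0.0055), among them CYC7 at 4.30 and the repressor ROX1 at 2.42 in the authors' deposited table. The 26 heat shock chaperones moved both ways, 10 up and 9 down (10 and 9 adjusted over the list alone; median -0.12, adjusted p = 0.32 for a shift up). HSP42 rose by 4.23, HSP26 by 3.69 and SSA4 by 2.17 in the authors' deposited table.

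Of 67 ribosome biogenesis genes 48 fell in the wild type and 0 rose (48 and 0 adjusted over the list alone; median -1.10, adjusted p = 1.1e-13). The GTPase NOG1 was at -2.87 and RRP5 at -2.71 in the authors' deposited table. Of 137 cytosolic ribosomal protein genes 38 fell and 1 rose (32 and 1 adjusted over the list alone; median -0.49, adjusted p = 6.7e-05). RPS9A was at -1.74 and RPS28B at -1.22 in the authors' deposited table. Of 34 translation factors 19 fell and 0 rose (19 and 0 adjusted over the list alone; median -0.61, adjusted p = 0.001), among them the initiation factor subunit NIP1 at -1.98 and TIF4631 at -1.38 in the authors' deposited table. All 8 histone genes fell (8 adjusted over the list alone; median -1.05, adjusted p = 0.0055). HHF2 was at -1.46 and HTA1 at -1.35 in the authors' deposited table. Of 18 cell cycle regulators 13 fell and 1 rose (13 and 1 adjusted over the list alone; median -1.46, adjusted p = 3.6e-10). Of 11 mitochondrially encoded genes on the list 3 were analysed, of which 1 fell (1 adjusted over the list alone; median -1.43, adjusted p = 0.0139). With signed z values in place of log2 changes, which allow for the wide errors of these genes, that call was lost (adjusted p = 0.4905). COX1, a subunit of the enzyme azide inhibits, was at -1.95 in the authors' deposited table.

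The other lists did not pass in the wild type. Counts adjusted over the list alone were the same for them, except for the alpha mating type genes. Of 17 P-body components 3 rose and 3 fell (adjusted p = 0.68). EDC2 was at 1.91 and the exonuclease XRN1 at -1.49 in the authors' deposited table. Of 18 stress granule components 0 rose and 6 fell (0.10), including NRP1 at -2.03 and TIF4631 at -1.38 in the authors' deposited table. Respiratory and carbon lists gave 0 up and 1 down of 9 nuclear cytochrome c oxidase subunits (0.58), 6 and 2 of 30 other respiratory chain and ATP synthase genes (0.49), and 2 and 7 of 13 tricarboxylic acid cycle genes (0.29). Of the last, IDH2 was at -1.73 and CIT1 at 1.07 in the authors' deposited table. Glycolysis and fermentation genes gave 2 up and 1 down of 16 (0.32), hexose transporters 3 and 1 of 15 (0.68), and glucose-repressed carbon genes 7 and 0 of 19 (0.0906). Of 22 Aft1-type iron genes 4 rose and 5 fell (0.91), of 23 ergosterol genes 0 and 9 (0.0955), of 36 Gcn4-type amino acid genes 2 and 12 (0.0982), and of 20 methionine and sulfur genes 3 and 7 (0.29). ERG11, the target of azole drugs, was at -1.29 and MET6, methionine synthase, at -2.77 in the authors' deposited table. Proteasome genes gave 1 up and 3 down of 32 (0.53), Pdr1-type multidrug transporters 1 and 4 of 9 (0.37), mating type a genes 0 and 3 of 7 (0.0906), alpha genes 1 and 0 of 3 (0.91; 0 adjusted over the list alone) and meiosis and sporulation genes 3 and 1 of 13 (0.52). The proteasome gene regulator RPN4 was at 1.14, the transporter SNQ2 at -1.46 and the pheromone protease BAR1 at -2.12 in the authors' deposited table.

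By the authors' adjusted p, 2666 genes (42.0%) changed in the wild type, 1355 up and 1311 down, and 3686 did not pass. Scaled to equal totals of the reconstructed group means, which shifts the median gene by 0.15, the split became 1706 up and 970 down.

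**Figure D1:**
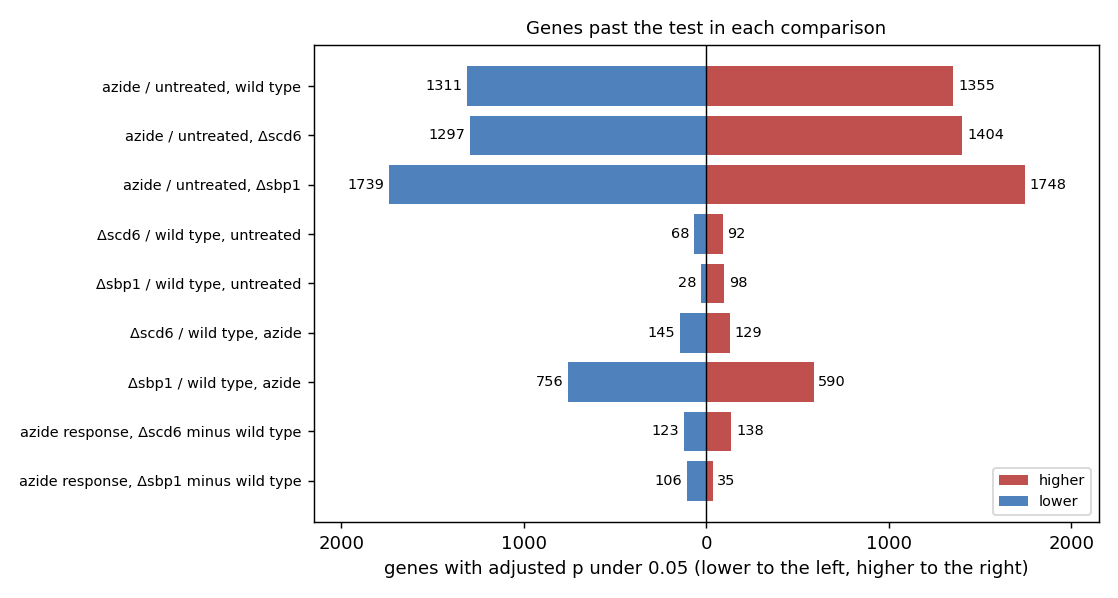
Number of genes past an adjusted p of 0.05 in each of 9 comparisons, with higher calls drawn to the right of 0 and lower calls to the left. The wild type azide response has 1355 higher and 1311 lower genes, and untreated Δscd6 against the wild type has 92 and 68.

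In Δscd6 cells azide again raised general stress genes and lowered ribosome biogenesis genes. The authors' deposited table listed rises of HSP30 (log2 change 7.24, adjusted p = 3.9e-30), FDH1 (6.93, 1.0e-20), COX26, a small protein of cytochrome c oxidase supercomplexes (6.22, 3.7e-42), FMP16 (5.61, 9.3e-57) and the small heat shock protein HSP42 (5.30, 1.2e-50). YER053C-A (5.21, 1.6e-56), the membrane stress protein HSP12 (4.92, 3.8e-18) and the transcription factor CIN5 (4.67, 4.6e-50) rose as well in the authors' deposited table. The falls by the authors' deposited table included the mucin MSB2, an osmosensor (-3.40, 1.7e-29), the mitochondrial tRNA modification gene MTO1 (-2.81, 8.2e-22), PHO84 (-2.61, 1.4e-12), GFD2 (-2.49, 4.3e-20) and HO (-2.46, 3.4e-27). Still larger falls in the authors' deposited table, of the subtelomeric helicase genes YRF1-5 (-6.90) and YRF1-4 (-5.90), and that of TAR1 in the ribosomal DNA (-3.41, 1.2e-05), lie in repeated sequence and are uncertain.

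Of the 30 general stress genes 27 rose in Δscd6 and 0 fell (28 and 0 adjusted over the list alone; median 2.55, adjusted p = 1.1e-33), including catalase CTT1 at 4.09 in the authors' deposited table. Of the 26 chaperones 13 rose and 1 fell (13 and 1 adjusted over the list alone; median 0.58, adjusted p = 1.9e-05). HSP26 was at 4.61 and BTN2, which sorts misfolded proteins, at 3.48 in the authors' deposited table. Of the 67 ribosome biogenesis genes 40 fell and 0 rose (41 and 0 adjusted over the list alone; median -0.69, adjusted p = 4.1e-06). NOP1 was at -2.24 and NSR1 at -2.15 in the authors' deposited table. Ribosomal protein genes gave 37 down and 1 up of 137 (25 and 0 adjusted over the list alone; median -0.54, adjusted p = 3.1e-05). RPS9A was at -1.24 in the authors' deposited table. Iron genes gave 13 down and 3 up of 22 (15 and 3 adjusted over the list alone; median -0.67, adjusted p = 0.0156). The cell wall mannoprotein FIT1 was at -2.23, the permease FTR1 at -1.83 and the mitochondrial carrier MRS4 at 2.12 in the authors' deposited table. With a preset correlation of 0.05 between genes the ribosomal protein and iron calls were lost (adjusted p = 0.0663 and adjusted p = 0.1108). With equal totals the medians became -0.15 for ribosomal protein genes, -0.28 for iron genes, -0.30 for ribosome biogenesis genes and 0.97 for chaperones. Such a scaling shifts all genes alike and so leaves the list test, a comparison with the other genes, as it is. Of the 3 mitochondrially encoded genes 2 rose (3 adjusted over the list alone; median 1.93, adjusted p = 4.8e-09), a call lost with signed z values (adjusted p = 0.3147). COX1 was at 1.83 in the authors' deposited table.

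Oxidative stress genes (8 up and 0 down, adjusted p = 0.0575), translation factors (0 and 11, 0.0575), cell cycle regulators (1 and 9, median -0.51, 0.0575), histones (0 and 5, 0.13) and hypoxic genes (3 and 6, 0.67) did not pass as lists in Δscd6. In total 2701 genes (42.5%) changed by the authors' adjusted p, 1404 up and 1297 down, and 3651 did not pass. With equal totals, a shift of 0.39 in the median gene, the split was 2493 up and 527 down.

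Azide in Δsbp1 cells raised general stress genes and lowered ribosome biogenesis genes, with the most calls of the 3 strains. Rises in the authors' deposited table included FDH1 (log2 change 7.17, adjusted p = 2.0e-23), HSP30 (6.64, 2.6e-27), YNR034W-A (5.60, 3.8e-71), TDA6 (5.60, 1.2e-47) and YER053C-A (5.37, 1.9e-67). COX26 (4.88, 1.7e-39), the aldehyde dehydrogenase ALD3, which shares sequence with ALD2 (4.80, 1.8e-68), and FMP16 (4.67, 3.0e-57) rose as well in the authors' deposited table. The falls by the authors' deposited table included PHO84 (-5.98, 3.2e-47), PCL1 (-5.95, 1.6e-62), the nucleolar protein NSR1 (-5.19, 1.3e-77) and MSB2 (-5.04, 6.0e-54). MAK16 (-4.48, 4.0e-34), the ATPase RIX7 (-4.40, 1.4e-54) and SPB1 (-4.40, 5.7e-51), all of ribosome assembly, and the sodium and phosphate symporter PHO89 (-4.38, 1.1e-45) fell as well in the authors' deposited table.

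Of the 30 general stress genes 27 rose in Δsbp1 and 1 fell (28 and 1 adjusted over the list alone; median 1.92, adjusted p = 3.0e-18). SPI1 was at 3.92 and RTN2 at 3.76 in the authors' deposited table. Of the 18 oxidative stress genes 11 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.75, adjusted p = 0.0144). GPX2 was at 2.10 and TSA2 at 2.01 in the authors' deposited table. Ribosome biogenesis genes gave 57 down and 1 up of 67 (59 and 1 adjusted over the list alone; median -1.89, adjusted p = 1.5e-24). Translation factors gave 25 down and 0 up of 34 (25 and 0 adjusted over the list alone; median -0.89, adjusted p = 7.4e-04). The elongation factor YEF3 was at -2.29 and TIF4631 at -1.83 in the authors' deposited table. Cell cycle regulators gave 15 down and 1 up of 18 (16 and 1 adjusted over the list alone; median -1.77, adjusted p = 1.5e-09). RNR1 was at -4.14 and CLB2 at -3.66 in the authors' deposited table. Amino acid genes gave 21 down and 2 up of 36 (21 and 2 adjusted over the list alone; median -0.65, adjusted p = 0.0236). Threonine deaminase ILV1 was at -2.19 and LEU9 at -1.96 in the authors' deposited table. The oxidative stress and amino acid calls were lost at a correlation of 0.05 (adjusted p = 0.0856 and adjusted p = 0.1837), and with equal totals the amino acid median was -0.37. All 3 mitochondrially encoded genes rose (3 adjusted over the list alone; median 4.39, adjusted p = 3.0e-08), a list call lost with signed z values (adjusted p = 0.261).

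Ribosomal protein genes (3 up and 34 down, adjusted p = 0.0849), histones (0 and 8, 0.0775), stress granule components (2 and 10, 0.0775) and chaperones (12 and 8, 0.15) did not pass as lists in Δsbp1. In total 3487 genes (54.9%) changed by the authors' adjusted p, 1748 up and 1739 down, and 2865 did not pass. With equal totals, a shift of 0.28 in the median gene, the split was 2416 up and 1211 down.

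Across genes, which are not independent replicates, the azide responses of Δscd6 and the wild type had a Pearson correlation of 0.71 and a Spearman correlation of 0.70, those of Δsbp1 and the wild type 0.85 and 0.83, and those of both deletion strains 0.81 and 0.85. No library entered more than 1 of these 3 responses. In both Δscd6 and the wild type 920 genes rose, where independent lists of these sizes share 299, and 755 fell, where they share 268, while 24 were called in opposite directions. For Δsbp1 and the wild type 1156 rose in both (373 if independent), 1089 fell in both (359) and 9 were opposite.

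**Figure D2:**
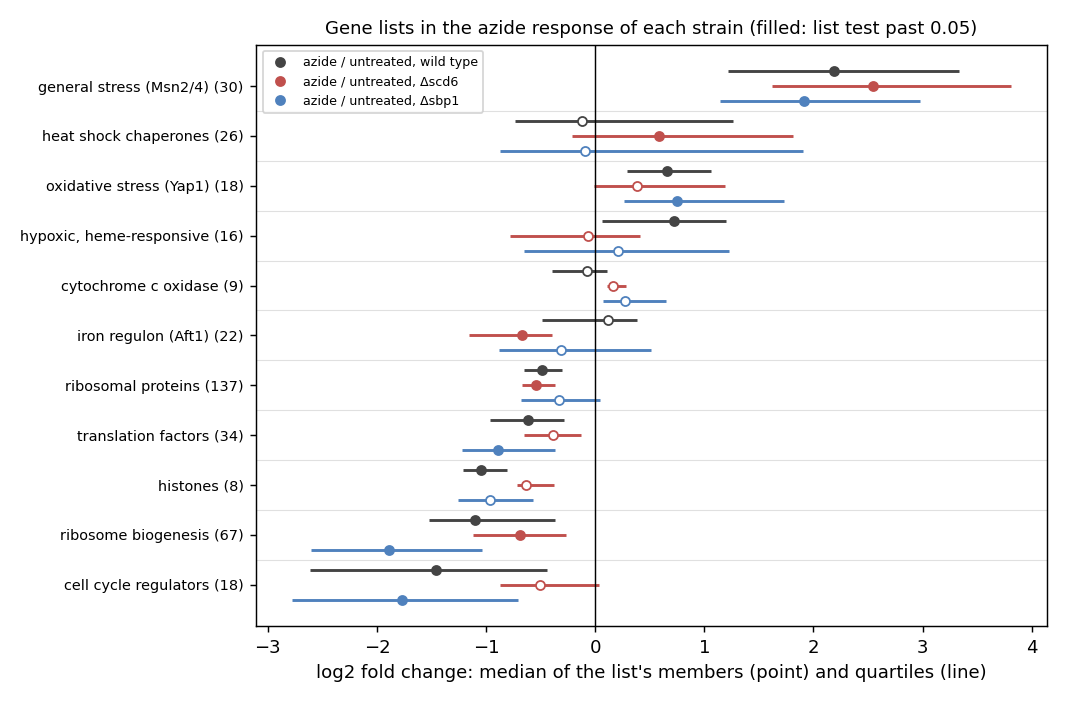
Median log2 change in azide over untreated for 11 gene lists in the wild type, Δscd6 and Δsbp1, with lines from the lower to the upper quartile of each list's genes, filled points where the list test passed an adjusted p of 0.05, and list sizes in brackets. General stress genes lie at 2.19, 2.55 and 1.92, and ribosome biogenesis genes at -1.10, -0.69 and -1.89.

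In untreated cells 160 genes differed between Δscd6 and the wild type by the authors' adjusted p, but 1244 with equal totals, so the extent of the change depends on the scaling. A total weighs abundant genes most, and the 20 most abundant held 22.2% of it in untreated Δscd6 against 18.8% in untreated wild type cells. Which scaling is nearer the truth was not tested. By the authors' deposited table CWP1, a cell wall mannoprotein (log2 change 1.72, adjusted p = 2.9e-09), AGA1, the anchor of a-agglutinin (1.49, 0.0102), and the ubiquitin ligase HUL4 (1.47, 2.9e-08) rose. Apart from SCD6 the falls in the authors' deposited table included YOR385W (-1.52, 0.0167) and PHR1, DNA photolyase (-1.37, 2.6e-04), which lie next to each other, FAA2, an acyl-CoA synthetase (-1.23, 5.4e-04), YGR127W (-1.18, 0.0055), RSC3, a chromatin remodelling subunit (-1.18, 0.0034), HAP4, an activator of respiratory genes (-1.08, 0.0134), and SIA1 (-1.07, 0.0126). Other rises in the authors' deposited table were of repeated genes whose reads cannot be assigned with certainty, among them YRF1-5 (6.18, 1.2e-58), YRF1-4 (4.94, 1.7e-49), TAR1 (3.12, 0.0016), the hexose transporter HXT7, near-identical to HXT6 (2.34, 0.0084), and YHR214W (1.35, 0.0126).

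Ribosomal protein genes had a median of 0.30 in untreated Δscd6 cells with quartiles at 0.20 and 0.46 (adjusted p = 1.9e-04), although 0 of 137 passed as single genes in either direction. Abundant members were RPL4A (0.45, 0.67) and RPL3 (0.22, 0.80) in the authors' deposited table. Glycolysis genes also had 0 passing members and a median of 0.43 (adjusted p = 0.0481), and of the 16 hypoxic genes 2 rose (4 adjusted over the list alone; median 0.32, adjusted p = 0.0294). The cell wall protein gene DAN1 was at 3.27 and TIR4 at 1.12 in the authors' deposited table. At a correlation of 0.05 these 3 calls were lost (adjusted p = 0.1535 for ribosomal protein genes, adjusted p = 0.16 for glycolysis and adjusted p = 0.1535 for hypoxic genes), and that of glycolysis also with signed z values (adjusted p = 0.1323). Their medians depend on the scaling and with equal totals were 0.02 for ribosomal protein genes, 0.15 for glycolysis genes and 0.05 for hypoxic genes. The 3 mitochondrially encoded genes had a median of -2.11 (adjusted p = 2.5e-11; 0 passing, 2 down adjusted over the list alone). They did not move together, OLI1 being at 0.43 and the weakly expressed VAR1 at -5.54 in the authors' deposited table, and the call was lost with ranks (adjusted p = 0.3648) and with signed z values (adjusted p = 0.1692). General stress genes (0 up and 0 down, adjusted p = 0.91), ribosome biogenesis genes (0 and 0, 0.33) and cell cycle regulators (0 and 1, 0.91) did not pass.

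In all, 160 genes (2.52%) differed between untreated Δscd6 and wild type cells by the authors' adjusted p, 92 higher and 68 lower. Equal totals move the median gene by -0.28 and give 63 higher and 1181 lower, and the fold changes fall with coding length across 5329 genes (Spearman correlation -0.41).

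Untreated Δsbp1 cells had higher general stress genes and lower genes of ribosome assembly. In the authors' deposited table the higher genes included HSP12 (log2 change 4.46, adjusted p = 2.0e-14), the stress gene DDR2 (2.91, 1.6e-07), SOL4 (2.62, 2.5e-17), hexokinase HXK1 (2.61, 1.0e-20) and glycogen phosphorylase GPH1 (2.05, 4.3e-15). YER053C-A (2.05, 4.3e-07) and CWP1 (1.95, 6.4e-12) were also higher in the authors' deposited table, as was HXT7 (2.08, 0.0233), whose near-identical neighbour makes it uncertain. Apart from SBP1 the lower genes in the authors' deposited table included BSC1 (-2.33, 0.002), PRM7 (-2.31, 7.9e-06), YOR385W (-1.67, 0.0049), the hypoxic translation factor ANB1 (-1.48, 1.2e-05), the cell wall protein TIR1 (-1.46, 0.0055), BTN2 (-1.16, 0.0072) and RRP12 (-1.05, 0.0157).

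Of the 30 general stress genes 21 were higher in untreated Δsbp1 cells and 0 lower (26 and 0 adjusted over the list alone; median 1.19, adjusted p = 6.4e-55). Ribosome biogenesis genes gave 5 lower and 0 higher of 67 (28 and 0 adjusted over the list alone; median -0.48, adjusted p = 5.0e-11). UTP20 was at -0.93 and the helicase DBP2 at -0.86 in the authors' deposited table. Ribosomal protein genes gave 1 lower of 137 (0 adjusted over the list alone; median -0.30, adjusted p = 1.4e-07). Translation factors (0 passing; median -0.23, adjusted p = 0.0264) and other respiratory genes (2 higher, 4 adjusted over the list alone; median 0.21, adjusted p = 0.0152) passed too. So did iron genes (2 lower, 3 adjusted over the list alone; median -0.04, adjusted p = 0.0152) and hypoxic genes (2 higher and 2 lower, 2 and 5 adjusted over the list alone; median -0.14, adjusted p = 0.0393). Those 4 calls were lost at a correlation of 0.05 (adjusted p = 0.1778, adjusted p = 0.1396, adjusted p = 0.1178 and adjusted p = 0.1492, in that order). Those of iron and hypoxic genes were also lost with ranks (adjusted p = 0.3369 and adjusted p = 0.1881) and with signed z values (adjusted p = 0.0758 and adjusted p = 0.126). The P-body list passed (adjusted p = 2.7e-08) with 1 of 17 members lower, SBP1 itself, and did not pass without SCD6 and SBP1 (adjusted p = 0.2207). With both genes kept, the P-body list also passed with ranks (adjusted p = 0.0144), at a median of -0.21 with quartiles at -0.32 and -0.07. The mitochondrially encoded genes had a median of -1.77 (adjusted p = 3.5e-12) with 0 of 3 passing, a call lost with signed z values (adjusted p = 0.0758). By the authors' adjusted p 126 genes (1.98%) differed, 98 higher and 28 lower.

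**Figure D3:**
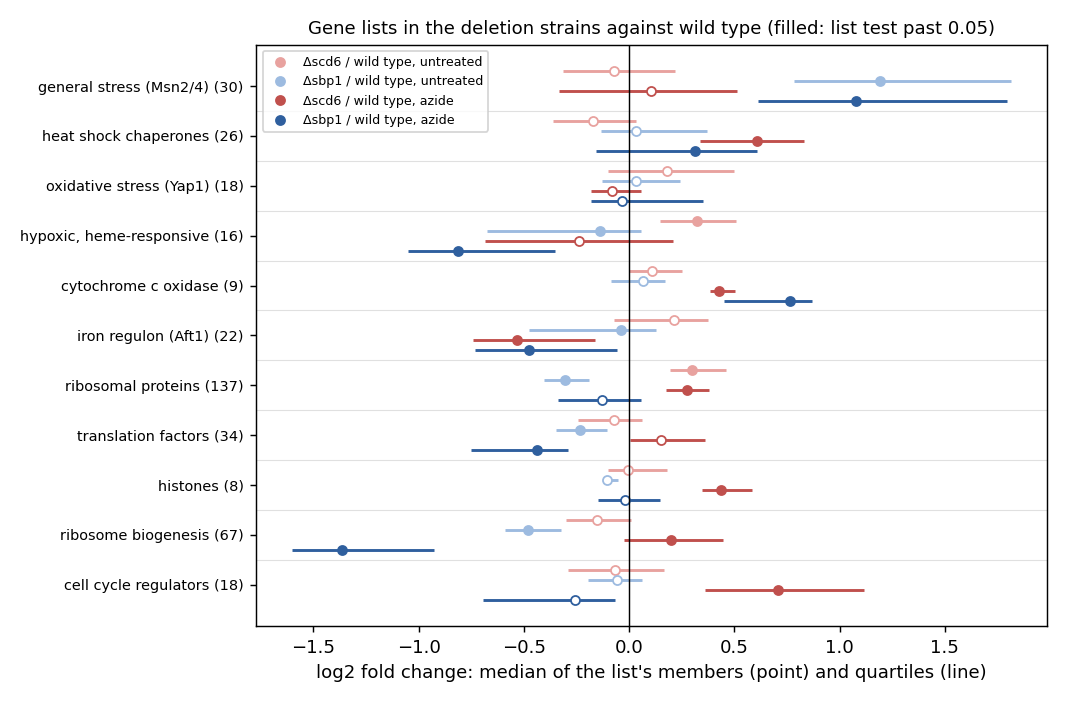
Median log2 change of 11 gene lists in each deletion strain against the wild type, untreated and in azide, with lines from the lower to the upper quartile of each list's genes, filled points where the list test passed an adjusted p of 0.05, and list sizes in brackets. General stress genes lie at 1.19 in untreated and 1.08 in azide-treated Δsbp1 cells, and cell cycle regulators at 0.71 in azide-treated Δscd6 cells.

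Under azide, Δscd6 cells had higher levels of cell cycle and chaperone genes than the wild type and lower levels of iron uptake genes. The authors' deposited table gave PCL1 (log2 change 2.98, adjusted p = 6.5e-21), CLN1, a G1 cyclin (2.19, 6.6e-15), CWP1 (1.75, 2.8e-09), PHO84 (1.65, 1.1e-04) and BTN2 (1.54, 2.4e-05) as higher. POP8, a subunit of RNase P and RNase MRP (1.51, 7.2e-04), YLR264C-A (1.38, 0.0064) and TMA10 (1.36, 0.0046) were higher as well in the authors' deposited table. Besides SCD6 the lower genes of the authors' deposited table included TPO2 (-2.19, 2.8e-11), PRM7 (-2.11, 2.4e-05), STP4 (-2.08, 9.0e-05), ROG3, an arrestin-related protein (-1.99, 2.7e-08), BSC1 (-1.93, 0.0042), TDA6 (-1.76, 7.1e-06) and TIR4 (-1.68, 1.6e-05).

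Of the 18 cell cycle regulators 9 were higher in azide-treated Δscd6 cells and 0 lower (12 and 0 adjusted over the list alone; median 0.71, adjusted p = 2.2e-16). CLB6 was at 2.62 and CLB2 at 1.33 in the authors' deposited table. Of the 26 chaperones 8 were higher and 0 lower (14 and 0 adjusted over the list alone; median 0.61, adjusted p = 1.9e-08). HSP10 was at 1.01 and SSA4 at 0.98 in the authors' deposited table. Iron genes gave 4 lower and 0 higher of 22 (10 and 0 adjusted over the list alone; median -0.53, adjusted p = 2.9e-05). FIT2 was at -1.17 and the reductase FRE4 at -0.88 in the authors' deposited table. Ribosomal protein genes (1 higher, 1 adjusted over the list alone; median 0.27, adjusted p = 3.5e-06) and histones (1 higher, 4 adjusted over the list alone; median 0.44, adjusted p = 0.0113) were shifted up. So were nuclear cytochrome c oxidase subunits (0 higher, 2 adjusted over the list alone; median 0.43, adjusted p = 0.0117) and mating type a genes (0 passing; median 0.45, adjusted p = 0.0073). The cytochrome c oxidase call was lost once the trend over coding length was taken out (adjusted p = 0.0831). Meiosis genes were shifted down (0 passing; median -0.35, adjusted p = 0.0073). Ribosome biogenesis genes (6 higher, 9 adjusted over the list alone; median 0.20, adjusted p = 0.0045) and glucose-repressed genes (1 lower, 1 adjusted over the list alone; median -0.19, adjusted p = 0.0438) lost their calls at a correlation of 0.05 (adjusted p = 0.099 and adjusted p = 0.139), the latter also with signed z values (adjusted p = 0.0891) and without the length trend (adjusted p = 0.0787). Of the 3 mitochondrially encoded genes 1 was higher (2 adjusted over the list alone; median 2.81, adjusted p = 2.1e-26). That median is the value of the weakly expressed VAR1, which did not pass (adjusted p = 0.36), nor did COX1 (1.67, 0.19), in the authors' deposited table. The list test leaves out the wide errors of these 3 genes, so its small p-value does not measure the strength of the evidence. General stress genes gave 5 higher and 2 lower (adjusted p = 0.49). In total 274 genes (4.31%) differed by the authors' adjusted p, 129 higher and 145 lower.

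Azide-treated Δsbp1 cells had lower ribosome biogenesis genes and higher general stress genes than the azide-treated wild type. Higher genes in the authors' deposited table included HXT7 (log2 change 2.82, adjusted p = 8.8e-05, uncertain as above), HXK1 (2.73, 9.1e-23), TMA10 (2.38, 1.6e-09), the reticulon RTN2 (2.25, 6.8e-16), ALD3 (2.25, 1.3e-18), HSP26 (2.23, 1.3e-18), DCS2 (2.13, 8.9e-20) and RGI1 (2.12, 6.5e-16). Besides SBP1 the lower genes of the authors' deposited table included BSC1 (-3.17, 4.1e-08), NSR1 (-3.06, 5.0e-31), TOS6 (-2.86, 2.3e-06), PRM7 (-2.85, 3.2e-10), RIX7 (-2.81, 2.6e-22), MAK16 (-2.61, 1.3e-12) and the nucleolar chaperone SRP40 (-2.61, 1.6e-16).

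Of the 67 ribosome biogenesis genes 60 were lower in azide-treated Δsbp1 cells and 0 higher (63 and 0 adjusted over the list alone; median -1.36, adjusted p = 3.0e-35). NOP1 was at -2.49 and UTP13 at -2.08 in the authors' deposited table. Of the 30 general stress genes 22 were higher and 0 lower (23 and 1 adjusted over the list alone; median 1.08, adjusted p = 1.2e-18). Nuclear cytochrome c oxidase subunits gave 5 higher of 9 (6 adjusted over the list alone; median 0.76, adjusted p = 0.0051). COX5B was at 1.19 and COX12 at 1.05 in the authors' deposited table. Other respiratory genes gave 8 higher of 30 (9 adjusted over the list alone; median 0.46, adjusted p = 3.5e-04). Hypoxic genes gave 2 higher and 7 lower of 16 (2 and 7 adjusted over the list alone; median -0.81, adjusted p = 0.0051). TIR1 was at -2.13 and CYC7 at 2.10 in the authors' deposited table. At a correlation of 0.05, 4 lists shifted down lost their calls. These were translation factors (14 lower, 16 adjusted over the list alone; median -0.44; adjusted p = 0.0051 became adjusted p = 0.0732) and amino acid genes (14 lower, 16 and 1 higher adjusted over the list alone; median -0.39; adjusted p = 0.0068 became adjusted p = 0.0925). The others were stress granule components (7 lower, 9 adjusted over the list alone; median -0.49; adjusted p = 0.018 became adjusted p = 0.0925) and iron genes (5 lower, 7 adjusted over the list alone; median -0.48; adjusted p = 0.018 became adjusted p = 0.0948). So did the shift up of chaperones (6 higher and 1 lower, 6 and 1 adjusted over the list alone; median 0.31; adjusted p = 0.0366 became adjusted p = 0.1594) and of proteasome genes (1 higher, 0 adjusted over the list alone; median 0.30; adjusted p = 0.0323 became adjusted p = 0.1594, and adjusted p = 0.0713 without the length trend). All 3 mitochondrially encoded genes were higher (3 adjusted over the list alone; median 4.04, adjusted p = 1.7e-22). That median is the value of the weakly expressed VAR1 (adjusted p = 0.0437 in the authors' deposited table). The list test leaves out the wide errors of these genes, so its small p-value does not measure the strength of the evidence. Cell cycle regulators (5 lower, adjusted p = 0.0606) and ribosomal protein genes (4 lower, adjusted p = 0.37) did not pass. In total 1346 genes (21.2%) differed by the authors' adjusted p, 590 higher and 756 lower. With equal totals, a shift of 0.13 in the median gene, the split was 996 and 574.

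Both deletion strains were compared with the same wild type libraries, so their differences share chance values. Untreated, 3 genes were higher and 1 lower in both strains, where independent lists of these sizes share 1.42 and 0.30, and 0 were opposite. In azide 36 were higher and 29 lower in both, where independent lists share 11.98 and 17.26, and 30 were opposite, for which no chance value was taken. In 100 simulations of unchanged groups against shared controls the fold changes had a Pearson correlation of 0.50 across genes in either condition, where the observed value was 0.18 untreated and 0.28 in azide. The covariance of the fold changes across genes was 0.0463 untreated, where the simulated covariance was 0.0474, and 0.0766 in azide, where it was 0.0431. Groups of 2 libraries could not be split, so part of the overlap may come from the shared controls. In untreated cells the shared controls alone could give the whole covariance.

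The azide response of Δscd6 differed from that of the wild type in 261 of 6331 genes, 138 with a positive difference and 123 with a negative one. A positive difference means that a gene rose more or fell less in the deletion strain than in the wild type. This test took the difference of both responses with standard errors implied by the deposited p-values and is not one of the authors' comparisons. PCL1 (2.53 ± 0.39 SE, adjusted p = 7.4e-08), CLN1 (2.03 ± 0.34, 2.1e-06) and SPB1 (1.84 ± 0.35, 4.4e-05) fell less in Δscd6, PCL1 by -1.39 against -3.92 in the wild type in the authors' deposited table. BTN2 (2.21 ± 0.43, 6.9e-05) and PHR1 (2.03 ± 0.36, 7.8e-06) rose more, BTN2 by 3.48 against 1.27 in the authors' deposited table. TIR4 (-2.80 ± 0.43, 7.2e-08) rose in the wild type and fell in Δscd6, and ROG3 (-2.34 ± 0.44, 2.9e-05) rose less. Further negative differences were -6.03 ± 0.57 for YRF1-5, -4.89 ± 0.48 for YRF1-4 and -3.18 ± 0.96 for TAR1 (0.0324), the last 3 in repeated sequence.

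Cell cycle regulators had a median difference of 1.03 between Δscd6 and the wild type, with 9 of 18 higher and 0 lower (11 and 0 adjusted over the list alone; adjusted p = 1.2e-06). Chaperones had 3 of 26 higher (16 adjusted over the list alone; median 0.81, adjusted p = 2.1e-05), including HSP82 at 1.18 and HSP78 at 1.06. Iron genes had 3 of 22 lower (6 adjusted over the list alone; median -0.60, adjusted p = 9.3e-04). FIT2 was at -1.65 and FIT1 at -1.34. Hypoxic genes had 2 of 16 lower (2 adjusted over the list alone; median -0.66, adjusted p = 0.0048). Mitochondrially encoded genes had 2 of 3 higher (3 adjusted over the list alone; median 3.78, adjusted p = 1.0e-32), while OLI1 did not pass (3.36, 0.15). The list test leaves out the wide errors of these genes, so its small p-value does not measure the strength of the evidence. Ribosome biogenesis genes had 5 of 67 higher (7 adjusted over the list alone; median 0.34, adjusted p = 0.0089), a call lost at a correlation of 0.05 (adjusted p = 0.243). With equal totals the median was 0.58 for these, -0.36 for iron genes and -0.42 for hypoxic genes. General stress genes had 2 higher and 1 lower (adjusted p = 0.53). SPI1 was at -1.59 and HXK1 at 1.55. With equal totals the split of 138 and 123 became 614 and 96, and with the trend over coding length taken out 60 and 121.

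The azide response of Δsbp1 differed from that of the wild type in 141 of 6329 genes, 35 with a positive difference and 106 with a negative one, by the same kind of test. It subtracts the same wild type response as the test for Δscd6, so the differences of both strains share chance values. Ribosome biogenesis genes fell further than in the wild type: 16 of 67 had a negative difference and 0 a positive one (34 and 0 adjusted over the list alone; median difference -0.80, adjusted p = 7.0e-15). Genes that fell further included MAK16 (-2.55 ± 0.48 SE, adjusted p = 8.5e-05), NSR1 (-2.48 ± 0.36, 3.9e-08), RIX7 (-2.39 ± 0.36, 1.5e-07) and TOS6 (-2.46 ± 0.73, 0.037), of which TOS6 did not pass in the wild type. HSP12 (-2.37 ± 0.71, 0.0387) rose less, and was already higher in untreated Δsbp1 cells. Apart from the residual signal of SBP1 itself (2.01 ± 0.44, 0.0014), positive differences included YNL195C (1.70 ± 0.37, 0.0011), FMP23 (1.56 ± 0.45, 0.0284), the glutathione peroxidase GPX1 (1.45 ± 0.40, 0.0182) and ALD3 (1.42 ± 0.37, 0.0118). Mitochondrially encoded genes had 2 of 3 higher (3 adjusted over the list alone; median 5.82, adjusted p = 1.1e-53), while VAR1 did not pass (6.28, 0.11). The list test leaves out the wide errors of these genes, so its small p-value does not measure the strength of the evidence. Ribosomal protein genes (0 passing; median 0.15, adjusted p = 0.04) and cytochrome c oxidase subunits (0 passing, 2 adjusted over the list alone; median 0.48, adjusted p = 0.0284) lost their calls at a correlation of 0.05 (adjusted p = 0.2772 and adjusted p = 0.0855) and with the length trend taken out (adjusted p = 0.1453 and adjusted p = 0.1549). With equal totals the ribosomal protein median was 0.28. General stress genes gave 1 higher and 3 lower (2 and 4 adjusted over the list alone; median -0.01, adjusted p = 0.17). With equal totals the split of 35 and 106 became 49 and 61.

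**Figure D4:**
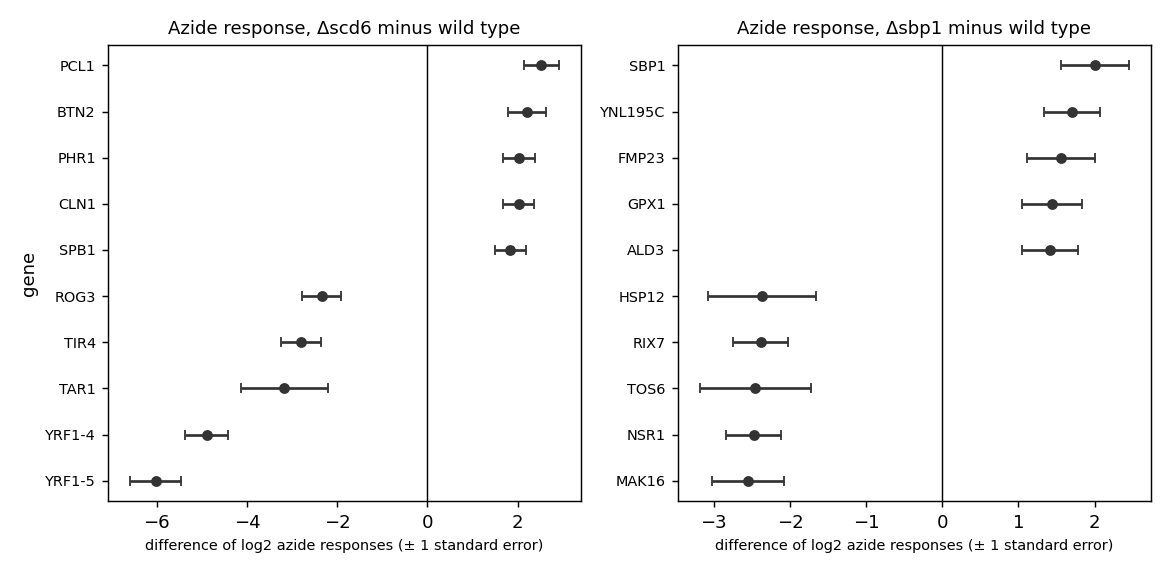
Difference of the log2 azide response of each deletion strain from that of the wild type for 10 named genes per strain, with bars of 1 standard error implied by the deposited p-values. PCL1 lies at 2.53 ± 0.39 in Δscd6, and NSR1 at -2.48 ± 0.36 in Δsbp1.

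Of 243 list tests over all 9 comparisons 68 passed, and 46 of these passed with a preset correlation of 0.05 between genes in place of 0.01. The lists that lost their calls at that correlation are named above with that adjusted p. An estimated correlation needs values per library and was not used here.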

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

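All tests of explanations given here were chosen after the results were seen, except that of coding length for ribosomal protein genes, and so were the comparison of both deletion strains and the scaling and length settings.

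Azide responses that differ between strains, by the test of the difference itself, are the results to look at again: 261 genes for Δscd6 against the wild type, 141 for Δsbp1 against the wild type and 342 for Δsbp1 against Δscd6. A difference is positive where a gene rose more or fell less in the strain named first. For Δscd6 the median difference was 0.81 for chaperones, 0.34 for ribosome biogenesis genes, -0.60 for iron genes, -0.66 for hypoxic genes, 1.03 for cell cycle regulators and 3.78 for mitochondrially encoded genes. Of these list calls that of ribosome biogenesis genes was lost at a correlation of 0.05 (adjusted p = 0.243), and those of iron and hypoxic genes at 0.1 (adjusted p = 0.1152 and adjusted p = 0.1295). For Δsbp1 it was 0.15 for ribosomal protein genes, -0.80 for ribosome biogenesis genes, 0.48 for cytochrome c oxidase subunits and 5.82 for mitochondrially encoded genes. Those of ribosomal protein genes and oxidase subunits were lost at a correlation of 0.05 (adjusted p = 0.2772 and adjusted p = 0.0855) and with the length trend taken out (adjusted p = 0.1453 and adjusted p = 0.1549). Single genes for Δscd6 were PCL1 at 2.53, BTN2 at 2.21, PHR1 at 2.03, CLN1 at 2.03, SPB1 at 1.84, TIR4 at -2.80, ROG3 at -2.34, and the repeated genes YRF1-5 at -6.03, YRF1-4 at -4.89 and TAR1 at -3.18. For Δsbp1 they were SBP1 at 2.01, YNL195C at 1.70, FMP23 at 1.56, GPX1 at 1.45, ALD3 at 1.42, MAK16 at -2.55, NSR1 at -2.48, TOS6 at -2.46, RIX7 at -2.39 and HSP12 at -2.37. Between the deletion strains, Δsbp1 minus Δscd6, PCL1 differed by -4.56, HSP12 by -3.38, PHO84 by -3.37, SPB1 by -3.08 and NSR1 by -3.04. Positive differences were YAR029W at 2.51, YNL195C at 2.47, and the repeated genes YRF1-5 at 4.74, TAR1 at 4.02 and YRF1-4 at 3.68.

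Tandemly repeated genes stood high in untreated Δscd6 cells: by 300-base words 9 of 9 were higher than in the wild type (median 3.46, quartiles 3.12 and 4.95), by 75-base words 14 of 16 (3.44, 1.91 and 4.94), among them ENA2 at 6.35, HXT6 at 3.46 and YRF1-5 at 6.18, while 2 were higher in untreated Δsbp1 cells by either. Reads with several matches kept in these libraries alone would raise distant repeats too, but by 300-base words their 13 genes had a median of 0.053 with 0 higher, and by 75-base words their 36 genes one of 0.199 with 2 higher and an upper quartile of 0.59. Genomic DNA would raise weakly expressed single-copy genes, whose 553 members had a median of -0.006. A lasting gain of copies would persist in azide, where the tandem genes had a median of -0.054 against the wild type by 300-base words and 0.007 by 75-base words. Neighbouring copies share sequence and so may share reads, and the tandem genes counted are not separate observations. A change in these repeats peculiar to the untreated cultures, or a gain of copies there alone, stays open as a hypothesis and may be technical or biological.

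Lists tied to growth were shifted in the deletion strains, while fold changes fell with coding length, most in untreated Δscd6 cells (Spearman -0.41) but also in the azide responses of Δsbp1 (-0.23) and the wild type (-0.18), and the ribosomal protein median in untreated Δscd6 cells depended on scaling (0.02 with equal totals). With the length trend of the other genes taken out, ribosomal protein genes kept a median of 0.24 (0.30 before; bootstrap interval 0.19 to 0.27) in untreated Δscd6 cells, and cell cycle regulators one of 0.84 (1.03 before; 0.499 to 1.195) in the difference of azide responses, which argues against length as the whole cause of either. For ribosome biogenesis genes in that difference, 0.19 remained of 0.34 (0.08 to 0.37), which leaves a length trend open. In Δsbp1 a response larger by 1 factor for every gene would leave nothing once the wild type response times the slope of 1.06 is taken away, but ribosome biogenesis genes kept -0.72 (-0.87 to -0.59), and with the length trend taken out their difference was -0.79 (-0.80 before; -0.90 to -0.66). The bootstrap intervals redraw the genes of a list, which are not independent, and do not measure the spread between libraries. Slower growth of the deletion strains, or a direct effect of either protein on these transcripts, was not tested and may underlie what remains.

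Mitochondrially encoded genes responded to azide in opposite directions: of 10 reading frames, 7 fell in the wild type (median -1.70), 6 rose in Δscd6 (1.86) and 10 rose in Δsbp1 (2.30). The 7 that fell are COX1 and the reading frames in its introns, which share 1 transcription unit, while OLI1 (adjusted p = 0.23), VAR1 (0.57) and SCEI (0.0661) did not pass in the wild type. Libraries of 1 group that differ in mitochondrial RNA are a candidate explanation, since it predicts a wide spread, and the implied errors of these genes were 1.85 times those of genes of like expression (quartiles 1.41 and 2.45), mostly those of that unit. Between the responses of the deletion strains 0 of the 10 differed (median 0.48), though with wide errors. Both differences from the wild type subtract the same wild type response, so they are not separate observations. Without values per library a difference between extractions and an effect of either deletion, which was not tested, stay open.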

How the results depend on the processing

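The scaling, length, repeat and description settings, the other error routes and all list settings were chosen after seeing the data; the thresholds and the filter on weakly expressed genes were chosen before. Requiring a 2-fold change left 1251 genes in the wild type azide response, 1283 in Δscd6 and 1963 in Δsbp1, and against the wild type 92 in untreated and 127 in azide-treated Δscd6, 75 in untreated and 535 in azide-treated Δsbp1 cells. An adjusted p under 0.01 left 59 and 81 genes in the untreated comparisons of Δscd6 and Δsbp1, 173 and 803 in those in azide, and 105 and 69 in the differences of their responses from the wild type. Both follow from the stricter threshold. Equal totals gave 1244 genes in place of 160 for untreated Δscd6 and 710 in place of 261 for its difference of responses. The setting moves all genes of a comparison by the same amount, -0.28 in the former. Taking out the length trend left 103 genes in untreated Δscd6 cells, 83 of them among the 160, and the cause was not tested. Every other count stayed within 1.5 times its reported value under these settings. The balance of calls turned with equal totals, from 92 higher and 68 lower to 63 and 1181 in untreated Δscd6 cells and from 590 and 756 to 996 and 574 in azide-treated Δsbp1 cells. Signs were compared for the 132 values of named genes only. With equal totals 130 kept their call and 2 did not pass, with 0 changes of sign. All 132 kept it with the median of ratios, which moved the median gene by less than 0.02. These genes were picked for the largest changes, of at least 1.05 in size, and equal totals moved no comparison by more than 0.39. Neither setting could therefore reverse a sign, and the median of ratios could hardly alter a call. Of the 68 list calls 46 were kept at a correlation of 0.05 and 27 at 0.1, 65 with ranks, 59 with signed z values, 68 without repeated genes, 68 without genes lacking a description, 67 without SCD6 and SBP1, and 63 without the length trend. With equal totals 0 of the 68 medians changed sign, but some nearly vanished: that of ribosomal protein genes went from 0.30 to 0.02 in untreated Δscd6 cells and from -0.54 to -0.15 in the azide response of Δscd6, and that of hypoxic genes from 0.32 to 0.05 in untreated Δscd6 cells. No paired analysis was possible because the tables hold no values per library. For the same reason the settings chosen before the data were seen that need such values were not run: other normalisations, a second count tool, no low-count filter, the pairwise fit, the replicate block, limma-voom, leaving out each library, other pseudocounts, a filter on library values and an estimated correlation. Depth is unknown, and in simulated data the difference test found 30 of 100 genes changed by 1 on the log2 scale in Δscd6, so many smaller differences would be missed.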

Other observations

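All lists in this part were chosen after the data had been seen. No list test is given for the Haa1-type and phosphate lists, which hold the genes that prompted them. List p-values in this part were adjusted over its 9 lists in each comparison, apart from the lists fixed before. Those 9 include the Haa1-type and phosphate lists, whose small p-values can lower the adjusted p of the others. Autophagy genes rose with azide: 12 of 31 in the wild type (median 0.50, adjusted p = 0.0028), 21 in Δscd6 with 2 lower (0.76, 3.7e-04) and 19 in Δsbp1 (0.67, 5.1e-04). ATG8, the ubiquitin-like protein of the autophagosome membrane, was at 2.06, 2.81 and 2.88 in the authors' deposited table. Subunits of RNA polymerases I and III, which transcribe ribosomal and transfer RNA, fell: 15 of 19 in the wild type (median -0.96, adjusted p = 6.0e-05), 16 in Δscd6 (-0.91, 7.0e-04) and 16 in Δsbp1 with 1 higher (-1.87, 3.7e-07). The largest subunit RPA190 was at -1.97, -1.39 and -2.90 in the authors' deposited table. In azide 15 of the 19 were lower in Δsbp1 than in the wild type (-1.18, 3.5e-08), and the difference of responses was -0.73 (adjusted p = 0.0018, 4 lower). Mitochondrial ribosomal proteins were higher in azide-treated Δscd6 (5 of 63, median 0.40, 2.2e-06) and Δsbp1 cells (11 of 63, 0.40, 5.3e-04) than in the wild type, and in untreated Δsbp1 cells as a list (0 of 63, median 0.19, adjusted p = 0.0129), a call lost at a correlation of 0.05 (adjusted p = 0.1476). They did not pass in any azide response (adjusted p = 0.46 in the wild type, 0.69 in Δscd6 and 0.77 in Δsbp1), nor did the responses of Δscd6 (0.25) or Δsbp1 (0.0849) differ from that of the wild type.

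Haa1-type genes for weak acid efflux, a list prompted by TPO2, SPI1 and HSP30 and so not independent of them, rose in 8 of 8 cases in the wild type (median 2.97), 6 in Δscd6 (2.33) and 8 in Δsbp1 (2.41), and 5 of 8 were lower in azide-treated Δscd6 than wild type cells (-0.81), TPO2 at -2.19 and TPO3 at -1.32 in the authors' deposited table. The difference from the wild type response had a median of -0.73 in Δscd6 (2 lower) and -0.80 in Δsbp1 (1 lower), and untreated Δsbp1 cells stood at 0.79 (2 higher). Of 17 phosphate-responsive genes, a list prompted by PHO84 and PHO89, which it holds, 10 were lower and 2 higher with azide in the wild type (median -1.21), 10 and 2 in Δscd6 (-0.76) and 12 and 2 in Δsbp1 (-1.47). The difference from the wild type response had a median of 0.07 in Δscd6 (3 higher, 1 lower) and -0.45 in Δsbp1 (4 lower). The acid phosphatase gene PHO12, at -3.68 in Δsbp1 in the authors' deposited table, is near-identical to PHO11. Transfer RNA synthetases fell in the wild type (10 of 19, adjusted p = 0.0144), while in Δscd6 (3 lower, 0.47) and Δsbp1 (8 lower, 0.0832) the list did not pass. Replication licensing genes fell in the wild type (7 of 15, 0.0144) and Δsbp1 (10 of 15, median -0.71, 0.0372), while in Δscd6 4 were lower and 1 higher (0.39). At a correlation of 0.05 these calls were lost (adjusted p = 0.0616 for synthetases, adjusted p = 0.0608 and adjusted p = 0.1043 for licensing genes), and for neither list did a difference of responses from the wild type pass (synthetases 0.16 in Δscd6 and 0.75 in Δsbp1, licensing 0.25 and 0.74). Peroxisome genes were higher in azide-treated Δsbp1 than wild type cells (5 of 27, 1 lower; adjusted p = 0.0359, and adjusted p = 0.1523 at a correlation of 0.05), and the 17 vacuolar proton pump genes did not pass as a list in any comparison.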
